A study of Mus musculus with 4 samples.

How the data were processed

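Genomic DNA of sorted mouse HSCs was extracted with the AllPrep DNA/RNA mini kit, converted with the EZ Methylation Lightning kit and made into libraries with NEBNext Ultra II, per the labels' protocols. Bisulfite turns unmethylated cytosines into uracil, so the share of cytosines kept at a site gives its methylation. The submitters' processing notes name FastQC, Trim Galore, Bismark 0.22.3 and Picard and the GRCm38 build. The region caller, its test, the coverage filter, the conversion rate and the gene annotation are not given in the sources used here.

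The authors deposited 1 table of differentially methylated regions with 31146 pairings of a region with a gene, which hold 24323 pairings of a region with a comparison, 22974 distinct regions and 13293 gene symbols. Per the file headers, each line gives the region, its number of CpG sites (a count), the methylation fraction of the 2 libraries compared, a test score, a p-value and an adjusted p-value, the linked gene and the distance from its TSS. The deposited fractions were multiplied by 100 to give percent. The score column holds no number in 114 lines and was not used. Which fraction belongs to which library was checked on regions with the same coordinates in 2 comparisons that share a library. Of 1304 such regions, 526 were equal within 0.01 points and 1293 within 10 points in the library named in both, while 0 were equal with the fractions exchanged in 1 of the comparisons. With the fractions exchanged in both, 101 were equal and 1029 within 10 points, fewer than with the fractions as named. All deposited adjusted p-values are at most 0.1, all differences exceed 10 points, no region is wider than 1001 bp, and all lines overlap the gene or the 5000 bp upstream of it.

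A list selected in this way shapes every number drawn from it. Regions without a listed difference are unknown, so a gene outside a list is not shown to be alike in both libraries, and levels over listed regions are not genome-wide levels. The authors' p-values compare 2 libraries and not the conditions. They also depend on depth, which the deposited table does not give, so the lengths of the lists can differ between comparisons for reasons of depth. Depth per library is unknown, no coverage minimum could be applied, and no interval that needs depth is given.

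Libraries were grouped by the genotype and treatment in the labels, with 1 library in each of the 4 groups: WT naive, WT infected, KO naive and KO infected. The first-named library minus the second gives each difference. Planned as promoter comparisons, the 4 comparisons were made on all listed regions, each counted once, because the table covers gene bodies as well. A region was called near a TSS when its midpoint lay within 1000 bp of the nearest linked TSS, otherwise upstream or in the gene body. The linked gene was taken from the authors' table, and 23.1% of regions are linked to more than 1 gene. Exons and introns were not told apart. Exact (Clopper-Pearson) 95% intervals on shares of regions treat regions as independent and cover counting error only.

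The 17 gene lists, with 483 members and 14 genes in more than 1 list, and the rule for naming genes were fixed before the data were examined. The rule names, per comparison, the 5 genes with the largest rise and the 5 with the largest fall, without predicted genes and large families, the 2 members of each list with the largest difference, and the DNA methylation machinery. Some further list members are named beside these as examples, and Erg and Il17ra among the 55 regions, chosen after their values were seen. A list's median over its listed genes was set against 10000 random lists of listed genes of the same size, matched on mean level in 20 bins, where at least 5 members were listed. The percentile describes these libraries and is not a test between conditions. All 483 members matched a symbol or synonym of the RefSeq gene table of the same build. Simulated lists of 20 genes were drawn from the real genes and shifted down by 30 points. Below the 2.5 percentile lay 40 of 40 for KO naive against WT naive and 40 of 40 for KO infected against WT infected. For WT infected against WT naive 31 of 40 did, and for KO infected against KO naive 39 of 40. Unshifted lists lay beyond the 2.5 or 97.5 percentile in 1, 1, 0 and 5 of 40. Smaller lists and shifts were not simulated, so a list that did not stand apart may still differ by less.

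Overlaps counted pairs of regions sharing at least 1 bp. For comparisons with a shared library, 3 unchanged libraries were simulated over 1000000 regions with 1% listed. Alternatives were a 20 point and a 5 point threshold, autosomes alone, centring on the median difference, regions with a value in all 4 libraries, 1 value per gene, intermediate levels, weighting by length, random lists without matching and, added after seeing the data, 10 or more sites, an adjusted p under 0.05, a single unadjusted p, other overlaps and the region nearest the TSS. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.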

Results

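Whole genome bisulfite sequencing was used to measure DNA methylation in mouse haematopoietic stem cells (HSCs), the bone marrow cells that renew themselves and give rise to all blood lineages. The cells were sorted by FACS as LK CD150+ CD48- cells. They were wild-type (WT) or lacked Dnmt3a (KO), the enzyme that adds methyl groups to previously unmethylated cytosines. Mice were naive or had been infected for 1 month with Mycobacterium avium, a bacterium that sets up a chronic infection. Each of the 4 groups held 1 library, so there are no replicates, no difference between conditions was tested, and the values below describe these 4 libraries. The measurements are a list of 24323 regions over 4 pairwise comparisons, already selected by the authors for a difference. No listed difference is under 10.02 percentage points and no region has fewer than 5 CpG sites. Read depth is unknown, so no value below carries an interval for its own precision. Coordinates are on GRCm38, a level is the percent of methylated cytosines, and a gene's level is the mean over its listed regions.

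Regions linked to Dnmt3a itself are given first, although a methylation list measures no deletion and checks none of the genotype labels. In KO infected against WT infected cells, 1 gene body region on chromosome 12 from 3871554 to 3872011, 65776 bp downstream of the transcription start site (TSS), stood at 14.6% against 46.5%. In KO infected against KO naive cells, the mean over 2 Dnmt3a regions was 15.8% against 38.6%. No Dnmt3a region was listed in KO naive against WT naive cells or in WT infected against WT naive cells.

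The first question was how the methylomes of KO and WT stem cells differ in uninfected mice. Methylation was lower in KO naive cells in 3419 of 4653 regions and higher in 1234, with a median difference of -19.2 points. Among the lower regions the median level was 63.0% in KO naive and 94.0% in WT naive cells. The stem cell genes among them included Mllt3, a regulator of HSC maintenance, at 40.4% against 95%. Hlf, a transcription factor of HSCs, stood at 25.8% against 66.5%, Fli1, an ETS factor, at 26.5% against 65.9%, and Kit, the stem cell factor receptor, at 30.6% against 66.3%. Away from promoters most regions were lower, with 82.5% of 3083 gene body regions and 83.0% of 481 upstream regions lower in KO naive cells. Within 1 kb of a TSS, 611 of 1089 regions were higher. Of those 611, 84.5% stood at exactly 0 in the WT naive library.

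By gene list, the HSC self-renewal and identity list had 12 of 32 members with a listed region in KO naive against WT naive cells, 10 lower and 2 higher by the mean over a gene's regions, and 7 lower and 5 higher by its region of lowest methylation. All 9 listed genes of the type I and II interferon response were lower. They included Mx1, an antiviral GTPase, at 55.3% against 86.0%, and the guanylate-binding protein gene Gbp3 at 11.7% against 44.3%. Psmb8 and Tap1, which serve antigen presentation, share a single region at 26.9% against 60.3%. Among 9 inflammatory genes 7 were lower, with Il6 at 52.1% against 89.6%. Of the transcription factors of development outside the Hox clusters 10 of 13 were higher, mostly from 0 in WT naive cells, as in Lhx9 at 23.2% against 0.0%. A region at 0 in WT naive cells can be listed only as higher. The list median of 11.6 points did not stand apart from the 11.1 of random lists matched on level, at the 61.4 percentile. The Hox clusters split into 5 lower, 5 higher and 1 within 10 points. Among cell cycle genes 6 of 7 were lower, and among lymphoid genes 5 of 9. Imprinted genes had 11 lower, 5 higher and 2 within 10 points, and their median of -11.8 points lay above that of 99.8% of random lists matched on level. Without matching it lay at the 90.7 percentile, and by the region of lowest methylation per gene the median turned to 15.7 points, with 8 lower and 10 higher. Some imprinted genes share a region in each comparison, such as Peg10 and Sgce in this one, so they are not independent. The other lists with at least 5 listed genes fell within the central range of random lists, and the 5.21 percentile of the interferon list was the lowest of them.

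The largest single falls by gene in KO naive against WT naive cells were Frg2f1 at 14.0% against 83.0%, Pgf at 7.5% against 75.8%, Chek2 at 24.3% against 91.9%, Elmod2 at 2.80% against 68.6% and Il6ra at 15.7% against 80.1%. Il6ra encodes the interleukin 6 receptor, and its region lies 4096 bp downstream of the TSS on chromosome 3 from 89909041 to 89909159. In the authors' deposited table this region has 7 sites and an adjusted p of 0.000497. The largest rises were Tbc1d9 at 79.2% against 13.6%, Camk1d at 100% against 40%, Rec8 at 92.2% against 36.2%, Myo3a at 84.0% against 32.6% and Syce1l at 94.6% against 47.8%. Rec8, a meiotic cohesin gene, has its region 161 bp upstream of the TSS on chromosome 14 from 55617821 to 55617931. With differences centred on the median of the listed ones, 50.6% of the regions still at least 10 points from 0 were lower, where 73.5% of all listed regions were lower without centring, since centring a selected list removes its own shift.

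**Figure D1:**
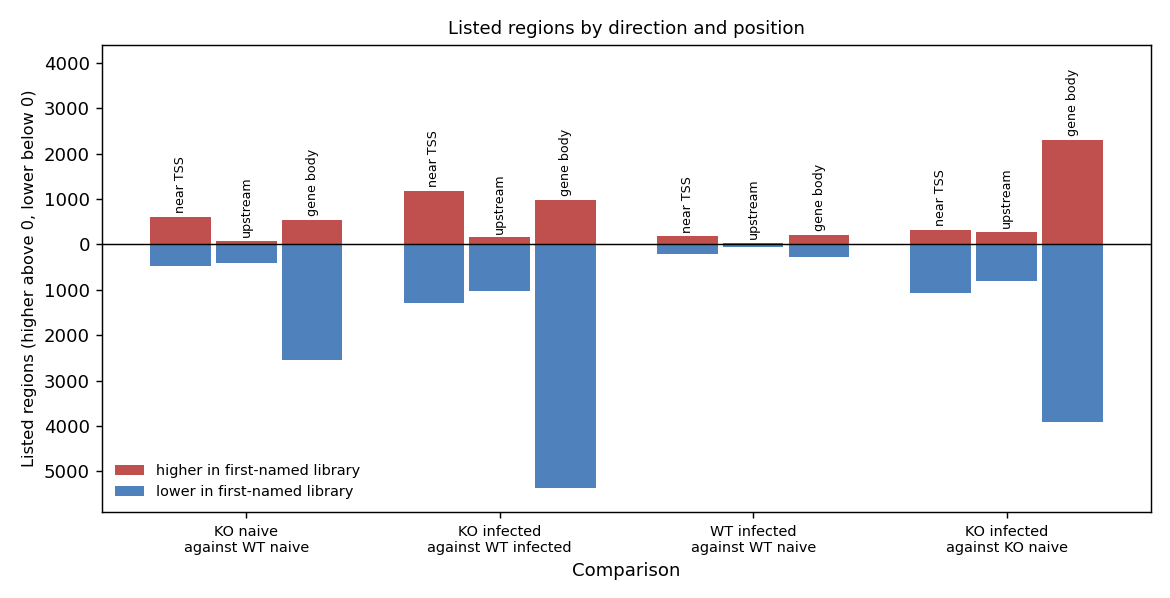
Number of listed regions (vertical axis) per comparison (horizontal axis) that were higher (red, above 0) or lower (blue, below 0) in the first-named library, in bars for regions near a TSS, upstream and in the gene body. Gene body regions were mostly lower in both genotype comparisons, 2542 of 3083 in naive and 5364 of 6352 in infected cells.

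The same genotype contrast was then made in infected mice, the comparison named in the series design. The list grew 2.15-fold, to 10012 regions, of which 7686 were lower in KO infected cells and 2326 higher. The median difference was -28.6 points, and the lower regions had medians of 31.9% in KO infected and 76.0% in WT infected cells. In the gene body 84.5% of 6352 regions were lower, and upstream 86.8% of 1178. Near a TSS 52.4% of 2482 regions were lower, 49.3% on the autosomes and 87.3% of 204 regions on the X. Of the 1182 higher regions near a TSS, 83.3% stood at 0 in the WT infected library.

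Stem cell genes were widely represented in KO infected against WT infected cells. Of the 32 genes of the HSC list 26 had a listed region, 23 of them lower, 2 higher and 1 within 10 points, and the list median was -36.0 points. Procr, which encodes the HSC surface marker EPCR, stood at 16.3% against 65.7%, in a region 4966 bp upstream of its TSS on chromosome 2 from 155746117 to 155746184. Levels were 24.5% against 72.8% for Hlf and 27.3% against 71.0% for Mllt3. The haematopoietic transcription factor genes Runx1, with 9 regions, and Mecom, with 7, stood at 34.5% against 82.7% and 30.1% against 72.2%. The list median sat at the 8.08 percentile of random lists matched on level, so its genes did not stand apart from other listed genes at similar levels. The Hox clusters had 17 lower, 3 higher and 1 within 10 points, with Hoxb7 at 20.1% against 71.4%, at the 10.5 percentile.

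**Figure D2:**
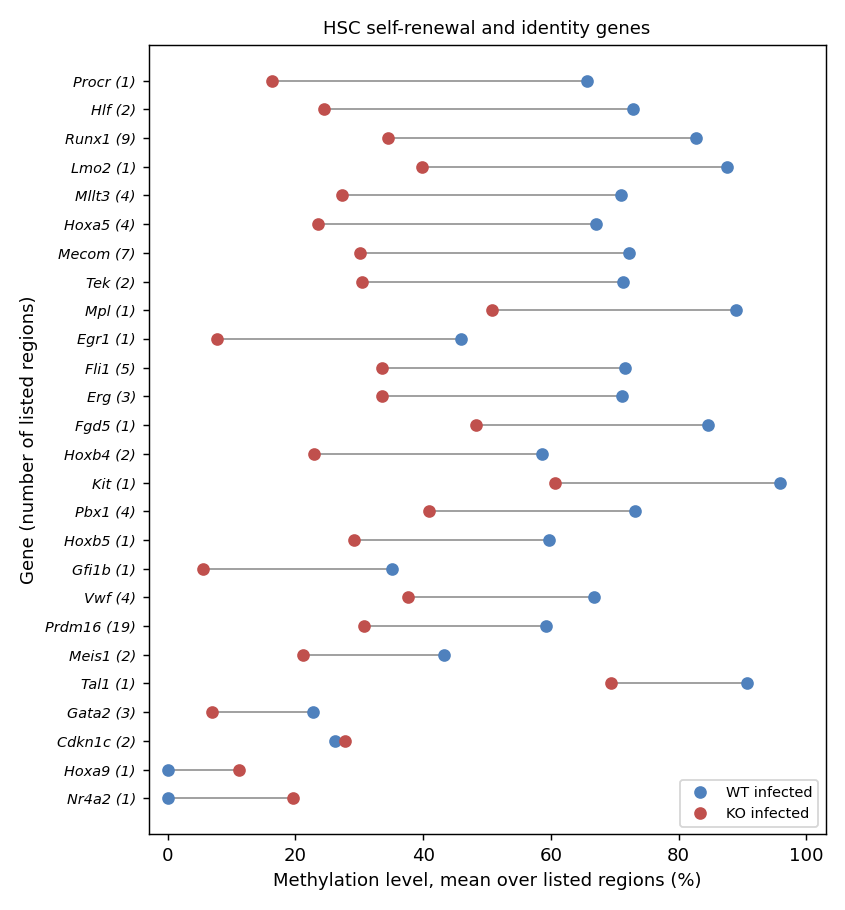
Methylation level in percent (horizontal axis, mean over the gene's listed regions) in WT infected (blue) and KO infected (red) cells for each listed gene of the HSC list (vertical axis, number of regions in brackets). KO infected was at least 10 points below WT infected in 23 of 26 genes and at least 10 points above it in Hoxa9 and Nr4a2.

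Of all genes listed in KO infected against WT infected cells, 73.6% were lower, which is the background for the lists that follow. All 9 listed genes of the type I and II interferon response were lower, with a median of -30.9 points that did not stand apart from the -32.5 of random lists, at the 64.0 percentile. Also lower were 7 of 10 genes of interferon gamma receptor signalling. Ifngr1, which encodes the ligand-binding chain of that receptor, stood at 24.6% against 73.5%, and Cd274, which encodes the immune checkpoint ligand PD-L1, at 40.3% against 85.0%. Among inflammatory genes 7 of 12 were lower, with Tnf at 18.9% against 73.9%. All 9 listed myeloid genes were lower, including Spi1, the gene of the myeloid factor PU.1, at 34.9% against 76.4%. Of the lymphoid genes 11 of 12 were lower, of the erythroid and megakaryocyte genes 4 of 5, and of the stroma and endothelium genes 7 of 8, among them Kdr, the VEGF receptor 2 gene, at 32.0% against 90.8%. All 8 listed genes of the DNA methylation machinery were lower. Among them Uhrf1, whose product recruits Dnmt1, stood at 34.5% against 80%, Tet1, a 5-methylcytosine oxidase gene, at 17.9% against 57.4%, and Dnmt3b at 2.58% against 18.8%. Of the apoptosis and p53 genes 4 of 5 were lower, but 2 of 5 by the region of lowest methylation, and of the cell cycle genes 6 of 10, with Mycn at 31.6% against 97.6%. Housekeeping genes, a control list, had 5 of 7 lower, and the developmental transcription factors 6 lower, 4 higher and 3 within 10 points. Imprinted genes had 12 lower and 8 higher of 21, and their median of -16.5 points lay above that of every random list drawn, whose median was -34.3. Without matching it lay at the 88.7 percentile, and by the region of lowest methylation the median turned to 16.6 points, with 9 lower and 12 higher. Peg10 and Sgce share regions here, as do Airn and Igf2r, while the random lists treat genes as independent.

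The largest falls by gene in KO infected against WT infected cells included a region on chromosome 2 from 37516354 to 37516421, 56 bp downstream of the TSS of Gpr21 and also inside Rabgap1 and Strbp, at 0.0% against 73.7%. In the authors' deposited table it has 6 sites and an adjusted p of 0.00492. Snx20, a sorting nexin gene, had 3 regions with a mean of 17.4% against 90.4%, and Phactr4 stood at 4% against 76.0%. The largest rises were a region shared by Med22 and Rpl7a at 92.9% against 39.3%, Cdh15 at 77.8% against 24.4%, Usp13 at 80.8% against 28.0% and Ptprd at 61.3% against 10%. After centring, 45.7% of the regions still at least 10 points from 0 were lower, where 76.8% of all listed regions were lower without it.

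Infection in WT cells gave the shortest list. Of 968 regions, 550 were lower and 418 higher in WT infected than in WT naive cells, with a median difference of -14.0 points. Regions within 1 kb of a TSS made up 40.5% of this list. The largest falls were Prdx4, a peroxiredoxin gene on the X, at 4% against 85.0%, and Ido1, an interferon-inducible enzyme of tryptophan breakdown, at 16.3% against 81.7%. Il15, a cytokine gene, stood at 0.0% against 62.0%, Smarca2 at 35.0% against 96.0% and Dnajb8 at 15.7% against 75.0%. The Ido1 region lies 70 bp upstream of its TSS on chromosome 8 from 24597028 to 24597130. In the authors' deposited table it has 6 sites and an adjusted p of 0.0128. The largest rises were Tmsb4x, also on the X, at 65.0% against 0.0%, Tbc1d9 at 72.2% against 11.9%, Cps1 at 97.6% against 46.4%, Psma3 at 59.6% against 9% and Epb41l4b at 100% against 50%. Tbc1d9 was also among the largest rises in KO naive against WT naive cells, through the same WT naive library. Its region from 83244385 to 83244462 was listed in both comparisons, at 0.0% in WT naive cells. The Epb41l4b region, from 57131907 to 57131915, has 5 sites, the fewest that a listed region has. Xist regions also differed between WT infected and WT naive cells, as given below for the sex chromosomes.

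In this shortest list, the fixed gene lists had between 0 and 8 members each. The interferon response had 1 of 47 members, Irf7, the master regulator of type I interferon, at 0.0% against 15.6%. Irf7 had the same values in KO naive against WT naive cells, without infection and through the same WT naive library. The HSC list had 3, with Hoxa9 at 17.0% and Hoxb5 at 18.9%, both against 0.0%, and Gata2 within 10 points. Myeloid genes were Csf2ra, a chain of the GM-CSF receptor, at 47.4% against 0.0%, Cd14 at 0.0% against 25.0% and Fcgr3 at 3.86% against 17.9%. An overlapping Csf2ra region stood at 41.0% in KO naive against 0.0% in WT naive cells, again without infection. The other Csf2ra region listed in that comparison was lower in KO naive cells. Imprinted genes had 8 members listed, 5 higher and 3 lower, with Nnat at 63.0% against 16.1%, Nap1l5 at 95% against 50% and Mest at 17.4% against 51.4%. The 6 listed Hox genes split into 3 lower and 3 higher. No gene of the inflammatory, erythroid or DNA methylation lists was listed. Of the regions still at least 10 points from 0 after centring, 30.7% were lower, where 56.8% of all listed regions were lower without it.

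Infection in KO cells gave 8690 regions, 8.98 times the WT number, or 4.82 times at a single unadjusted p and 4.2 times among regions of 5 to 7 sites. The difference between the numbers was not tested. Methylation was lower in KO infected than in KO naive cells in 5784 regions and higher in 2906, with a median difference of -19.6 points. The lower regions had medians of 32.1% in infected and 69.0% in naive cells, and the higher regions 97.2% and 78.6%. Near a TSS 76.9% of 1398 regions were lower, 74.8% on the autosomes and 88.2% on the X, and in the gene body 62.9% of 6203. Of the 323 higher regions near a TSS, 23.2% stood at 0 in the KO naive library, a smaller share than given above for the WT libraries.

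Hox genes were mostly lower in KO infected than in KO naive cells. Of 39 Hox genes 23 had a listed region and 21 of them were lower, with a median of -31.0 points against -22.6 for random lists matched on level, at the 0.66 percentile. By the region of lowest methylation per gene, 19 were lower and the median of -13.6 points lay at the 93.8 percentile, so the list no longer stood apart. Hoxb7 stood at 19.3% against 68.4%, and 1 of its 2 regions lies on chromosome 11 from 96289495 to 96289659, 2954 bp downstream of the TSS. Hoxb5 stood at 30.7% against 76.6% and Hoxb3 at 33.8% against 77.9%, while Hoxb13 and Hoxc13 were higher. Neighbouring Hox genes share some regions, so they are not independent. Of the HSC list 23 of 32 were listed, 18 lower and 3 higher, with Hlf at 16.4% against 50.6% and Mllt3 at 35.7% against 77.6%, but Kit at 81.9% against 54.3%.

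Of the interferon response genes 12 of 14 were lower in KO infected than in KO naive cells, where 67.6% of all listed genes were lower. The list median lay at the 21.6 percentile of random lists matched on level, so it did not stand apart. Psmb8, Psmb9 and Tap1, with 1 region each, all stood at 70.8% against 90.1%, so the 12 genes are not all independent. Igtp and Irgm2, both interferon-inducible GTPase genes, share a region at 25.1% against 64.9%, while Mx1 stood at 92.6% against 56.8%. Ifngr1 stood at 18.1% against 68.0% and Cd274 at 40.5% against 82.9%. Of the 9 myeloid genes 6 were lower, and Ctsg, the cathepsin G gene, was higher at 84.0% against 40.7%. Of the 9 stroma and endothelium genes 5 were lower, with Emcn at 14.3% against 72.5%. Germline genes had 3 lower and 2 higher of 6, or 3 and 3 by the region of lowest methylation, and housekeeping genes 7 lower and 2 higher of 10. Mature neutrophil and macrophage markers had 2 genes listed in each comparison but WT infected against WT naive, where 1 was listed. The list was meant as a check for cells outside the sort gate. Its counts cannot decide that, because such cells present alike in both libraries would list no region. Imprinted genes had 10 lower and 6 higher of 22, with a median of -5.42 points, above that of 99.99% of matched random lists and at the 92.5 percentile without matching. By the region of lowest methylation 15 were lower and 7 higher, with a median of -15.3 points.

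The largest falls by gene in KO infected against KO naive cells were Il2 at 17.4% against 90.8%, Snx20 at 9.52% against 82.7%, H2-Pa at 16.8% against 86.1%, Llph at 15.2% against 83.7% and Ctnnbip1 at 22.8% against 89.6%. The Snx20 region spans 88627150 to 88628070 on chromosome 8, 8518 bp downstream of the TSS. In the authors' deposited table it has 167 sites and an adjusted p of 1.25e-145. The largest rises were L3mbtl4 at 95.8% against 44.5%, Eps15l1 at 91.6% against 41.6%, Nmbr at 100% against 52.0%, Slc45a3 at 96.5% against 48.9% and Tbce at 78.0% against 31.0%. Over the 40 pairs of list and comparison with at least 5 listed genes, 4 lay beyond the central 95% of random lists, or 8 by the region of lowest methylation, where 2 would at the nominal rate. Unshifted simulated lists lay beyond in 5 of 40 for KO infected against KO naive and in 1, 1 and 0 of 40 for the other comparisons. Centring left 46.9% lower among the regions still at least 10 points from 0, where 66.6% of all listed regions were lower without it.

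Sex-linked regions differed between the libraries. Beside the X counts above, every listed region within 1 kb of the TSS of Xist, the RNA that silences the inactive X, was higher in KO infected cells, at 96.7% against 24.2% in WT infected and at 97.5% against 69.0% and 82.0% against 41.0% in KO naive cells. Within the same distance, 2 Xist regions were also higher in KO naive than in WT naive cells and 2 in WT infected than in WT naive cells, the widest differences being 74.5% against 43.9% and 57.6% against 36.2%. A Kdm5d region on the Y stood at 18.3% in KO infected against 0.0% in WT infected cells. Regions listed on the Y at Mid1-ps1 stood at 93.5% against 30.4% and 86.5% against 47.6% in that comparison. In KO infected against KO naive cells they stood at 93.1% against 36.3% and 85.9% against 63.3%. Reads were thus assigned to the Y in all 3 of these libraries, in KO naive cells at Mid1-ps1 alone. Whether the Mid1-ps1 reads are particular to the Y was not examined.

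**Figure D3:**
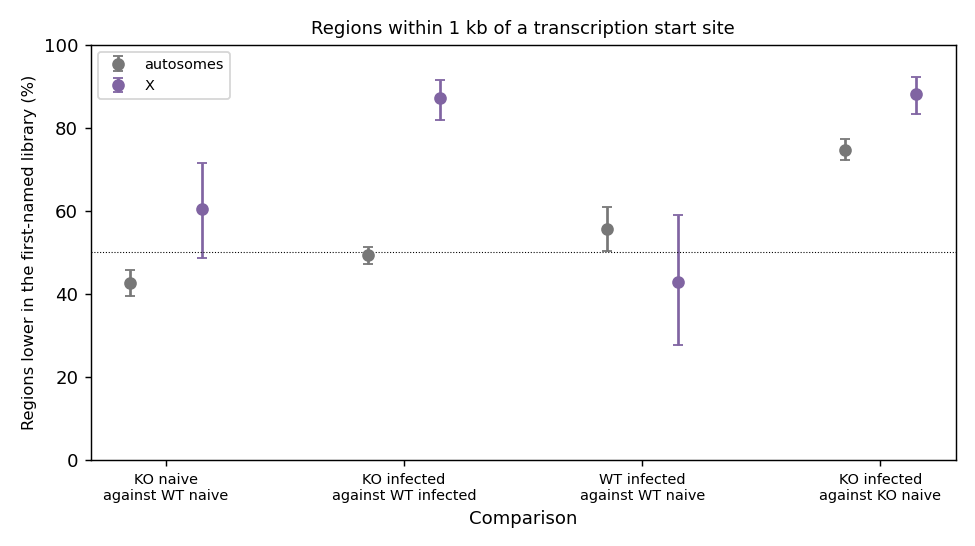
Percent of regions within 1 kb of a TSS that were lower in the first-named library (vertical axis) for each comparison (horizontal axis), on the autosomes (grey) and on the X (purple). Bars are exact 95% binomial intervals over regions, which cover counting error only, and the dotted line marks 50%. In KO infected against WT infected cells the X stood at 87.3% and the autosomes at 49.3%.

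Values in all 4 libraries could be assembled for 55 regions listed with the same coordinates in several comparisons. Their mean level was 72.4% in WT naive, 63.3% in WT infected, 44.7% in KO naive and 34.9% in KO infected cells. Over all regions with a value in the library, which differ between libraries, the mean was 61.2% in WT naive and 59.5% in KO naive cells. KO was below WT in both states in 47 of the 55, KO infected was the lowest of the 4 in 35, and WT naive was the highest in 40. Among these regions were a gene body region of Erg, a transcription factor gene of HSCs, at 66.9%, 46.9%, 27.9% and 16.2% in that order of libraries, and one in Il17ra at 65.6%, 55.2%, 31.6% and 12.1%. The infection difference in KO minus that in WT had a median of -2.0 points, was -10 or below in 13 regions and 10 or above in 9. The median infection differences were -9.48 points in KO and -8.89 in WT. These regions were selected for differences between the same libraries, so their order is not independent of the selection.

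**Figure D4:**
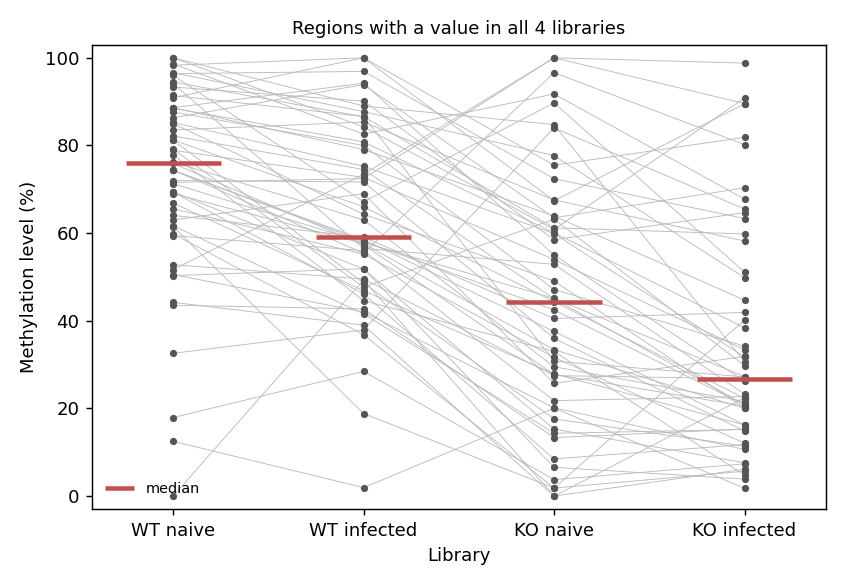
Methylation level in percent (vertical axis) of the 55 regions with a value in all 4 libraries (horizontal axis). Points are regions, grey lines join a region across libraries and red bars are medians, at 75.9%, 59.0%, 44.4% and 26.8% from left to right.

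The 2 genotype comparisons share no library, so their overlap was examined for direction. Of the KO naive against WT naive regions, 7.91% overlapped a region of KO infected against WT infected. Of 373 overlapping pairs, 317 went the same way, 85.0% against 66.0% given by the shares of lower regions among these pairs in each list. The gap was smaller with position and level taken into account. Of 346 autosomal pairs 86.7% went the same way, against 79.2% on average and 84.4% at most for directions drawn within such strata. The 2 infection comparisons also share no library. They overlapped in 84 pairs, of which 50 went the same way, 59.5% against 58.2% from the shares among these pairs. Comparisons with a shared library are tied by construction. KO infected against KO naive and KO infected against WT infected went the same way in 99.4% of 2483 pairs. KO naive against WT naive and WT infected against WT naive, which share WT naive, did so in 100% of 251 pairs. Those pairs took in 25.9% of the WT infected against WT naive regions. With a library shared in this way, 3 simulated unchanged libraries gave 100%. The direction of these overlaps can therefore neither show nor exclude a common effect.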

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

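The tests on the X chromosome, the share of regions around Dnmt3a and the direction of overlapping regions away from a TSS were chosen after the results were seen. The setting of a single unadjusted p was added after seeing the data, with its bound set before its result, as were the bounds of the other tests.

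Infection went in opposite directions in WT and KO cells in 34 of the 84 overlapping regions, and genotype in opposite directions in naive and infected cells in 56 of 373. These differences were not tested, since each group held 1 library. By gene, the infection differences in WT and KO were -19.6 and 16.0 points for Brdt, 47.4 and -21.3 for Csf2ra, 25.6 and -22.9 for H19, 17.0 and -12.7 for Hoxa9, 18.9 and -45.9 for Hoxb5, 45.0 and -17.2 for Nap1l5, and 46.9 and -14.6 for Nnat. They come from each comparison's own listed regions of the gene, which need not be the same region. For Csf2ra, WT naive cells at 0.0% also differed from KO naive cells, at 41.0% in an overlapping region, so its WT difference is not particular to infection.

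In the KO infected library, regions near a TSS on the X were lower than in WT infected cells far more often than on the autosomes, by 38.0 percentage points. That argues against the same loss acting on both in this comparison, although the same gap prompted the test. Against KO naive cells the gap was smaller, with 88.2% of near-TSS regions lower on the X and 74.8% on the autosomes. All listed regions within 1 kb of the Xist TSS were higher in KO infected cells than in the partner library, by at least 28.5 points. A larger share of male cells in that library would give both, because male cells lack the methylated inactive X and carry a methylated Xist promoter, and is a candidate explanation. The same pair of differences was seen in KO naive against WT naive cells, with Xist regions higher by 14.1 and 30.6 points and 60.5% of near-TSS regions lower on the X against 42.6% on the autosomes, but not in WT infected against WT naive cells, with Xist regions higher by 19.4 and 21.3 points and 42.9% lower against 55.7%. The animals' sex is not given in the sources used here. Reads at Kdm5d on the Y leave male cells open in WT infected cells too. KO naive cells had listed Y values at Mid1-ps1 alone, and whether those reads are particular to the Y was not examined. A direct effect of genotype or infection on the X was not tested.

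The list of infection differences was 8.98 times as long in KO as in WT cells. Without X and Y the ratio was 9.25, which argues against the sex chromosomes as the cause. At the same unadjusted p for all comparisons it was 4.82, and among regions of 5 to 7 sites 4.2. Neither a looser unadjusted p nor fewer sites in the WT lists alone accounts for the whole ratio, although the ratio was lower under each. These settings were not applied together, so what they account for jointly is unknown. Depth per site, which was not tested because the table does not give it, stays open, as does a difference between 2 single libraries. A larger response of KO cells to infection is a hypothesis that these lists cannot separate from those.

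Methylation away from a TSS was lower in KO cells in both genotype comparisons, which share no library. Overlapping autosomal regions went the same way in 86.7% of 346 pairs, while directions drawn at random within strata of position and level did so in 79.2% on average and in 84.4% at most over 10000 draws. That excess of 7.51 points over the mean is under the bound of 10 set beforehand. Over the 258 pairs away from a TSS 89.1% went the same way against 84.0% on average and 89.1% at most. By that bound chance differences between single libraries stay open, although no draw exceeded the observed share in either set of pairs. The draws agreed often because most regions were lower in KO cells in both lists. A loss spread over all regions would thus be in the draws too and add little to the excess. The test therefore cannot decide whether the lower methylation in KO cells is chance. For DNA of another strain around Dnmt3a, the planned ratio of 5.03 to the WT infection list rests on 1 region in that list, so it decides nothing and the explanation cannot be told apart by it. A share chosen afterwards was at most 0.52% of listed regions within 20 Mb of Dnmt3a, against 0.41% in KO infected against KO naive. The window holds 0.68% of reference genes, so the listed regions were not concentrated there. With so few genes in it, the window could hardly hold most of the regions whatever the cause, so the share decides no more than that. DNA of another strain elsewhere in the genome was not examined.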

How the results depend on the processing

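The 10 or more sites, adjusted p under 0.05, single unadjusted p, overlap, away-from-TSS and nearest-TSS settings were chosen after seeing the data. Of the counts, levels and shares that answer a comparison, 70 alternative values stayed close to the reported ones and 45 moved; the cause was not tested unless the setting itself removes regions. Counts below are given in the order KO naive against WT naive, KO infected against WT infected, WT infected against WT naive, KO infected against KO naive, where each moved. At 20 points 2228 regions were lower in KO naive and 314 in WT infected cells, and 273, 365, 198 and 993 were higher. Centred on the median, 1262, 2716, 185 and 2566 were lower by at least 10 points. Among regions listed in the comparison and with a value in all 4 libraries, 46, 45, 7 and 9 were lower and 4, 4, 1 and 4 higher. At mean levels of 10 to 90%, 395, 608, 244 and 1742 were higher, and 352 were lower in WT infected cells. With 10 or more sites 1245, 4422 and 178 were lower in the first 3 comparisons and 229, 568, 141 and 1320 higher. At an adjusted p under 0.05, 2103 were lower in KO naive against WT naive and 1638 higher in KO infected against KO naive. At 1 unadjusted p for all, 1744 and 3903 were lower in the genotype comparisons and 3410 in KO infected against KO naive, and 1414 and 1251 were higher in the comparisons with KO infected cells. The difference of infection differences was -20 or below in 6 regions, -5 or below in 25 and 5 or above in 17, and over regions overlapping in both infection comparisons 30 were lower and 32 higher. Over all regions with a value in the library, the mean level was 61.2% in WT naive and 59.5% in KO naive cells, in place of 72.4% and 44.7%, over different regions. With the region of lowest methylation per gene, 8 of 40 lists lay beyond the central range in place of 4, and 7 of 65 list medians changed sign. On autosomes alone none changed sign. Random lists without matching leave a list's own median as it is, so its sign could not change there. Csf2ra in KO naive against WT naive cells turned from 12.4 to -16.1 points with that region, and to -16.1 with the region nearest the TSS. Of the values of single genes, 322 stayed, 30 moved and 2 reversed. The 5 point threshold changes nothing for the 4 comparisons, since no listed difference is under 10 points. A coverage minimum and weighting by coverage were not run, because depth is unknown. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers.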

Other observations

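The genes that each comparison reaches were also counted, and differences between comparisons in these counts were not tested. Over the 68 pairs of gene list and comparison, 22 lay above the 97.5 percentile of random sets of genes of similar length and 1 below the 2.5 percentile. In KO infected against WT infected cells 26 of 32 HSC genes had a listed region, where random sets had a median of 11, and 21 of 39 Hox genes against 7. In KO infected against KO naive cells the numbers were 23 HSC genes against 10 and 23 Hox genes against 5. These lists were not alone. Imprinted genes were reached in 17 of 27 against 8 and in 19 of 27 against 7 in the same comparisons, myeloid genes in 9 of 23 against 3 in the second, and the housekeeping genes, a control list, in 10 of 30 against 5 there. Germline genes were reached less than random sets in KO infected against WT infected cells, at 2 of 33 against 9. Interferon response genes stood at 9 of 45 against 9 there, while interferon gamma receptor genes stood at 10 of 18 against 5 and inflammatory genes at 12 of 29 against 6. In KO infected against KO naive cells interferon response genes stood at 13 of 45 against 8. In KO naive against WT naive cells HSC genes stood at 12 of 32 against 7, Hox genes at 11 of 39 against 3. Imprinted genes stood at 13 of 27 and developmental transcription factors at 13 of 42 there, each against 5. Inflammatory genes stood at 9 of 29 and housekeeping genes at 8 of 30 there, each against 3. In WT infected against WT naive cells Hox genes stood at 6 of 39, imprinted genes at 6 of 27 and myeloid genes at 3 of 23, each against 1. Genes with enough covered sites are unknown, so these numbers mix methylation differences with CpG density and coverage.

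Imprinted genes, of which only 1 parental copy is methylated at the control regions, had single regions that differed either way. At Peg10, a region on chromosome 6 from 4747370 to 4747573 stood at 40.2% in KO infected and 7.19% in WT infected cells. Another from 4747928 to 4748202 stood at 17.0% in KO naive and 56.1% in WT naive cells. That region was also lower in WT infected than in WT naive cells, at 29.8% against 56.9%, so its difference is not particular to the genotype. At Kcnq1ot1, a region on chromosome 7 from 143296076 to 143296600 stood at 57.0% in KO infected and 39.6% in WT infected cells. It was also higher in KO infected than in KO naive cells, at 55.6% against 40.5%. No explanation was tested for these values.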
